A study of Arabidopsis thaliana with 15 samples.

How the data were processed

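RNA was extracted from leaves of Arabidopsis thaliana (Columbia) grown in a greenhouse under long days, and poly-A selected libraries were made with a NEBNext Ultra kit, per the labels' protocols. The data are 15 libraries of 5 genotypes, 3 per genotype, placed in groups by the genotype in the labels. The authors deposited a table of read counts per gene, which are whole numbers without normalization. Reads were aligned with HISAT2 2.0.5, per the submitters' processing notes. The counting tool, its strand setting, the genome build and the annotation release are not given in the sources used here. Because strand is not stated, reads from a gene and an overlapping or antisense partner cannot be told apart, and near-identical copies (the PDF1.2, LHCB1, LHCB2, RBCS and SAUR families) are uncertain singly. The table holds 33024 genes, of which 191 are unannotated loci named by the submitters. Of the identifiers, 32548 matched the TAIR10.1 annotation, and 32532 of these (99.95%) had the same start and end, so coordinates are given on that assembly. Gene symbols are those of the table. The annotation gives the symbols TOPP6 and TOPP7 the other way round, so these genes are also named by identifier.

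Before averaging, the replicates of each genotype were compared by a chi-square of their counts per gene, and every pair differed by more than sampling noise (5.87 to 27.5 per gene), so each library counts as 1 replicate. Total counts ran from 17962200 to 20756997 per library. Genes were kept by edgeR's filterByExpr with the genotypes as groups (minimum count 10, minimum total 15), which left 20037 genes, 150 of them unannotated loci. Libraries were scaled with TMM factors. A quasi-likelihood model with a mean per genotype was fitted to all 15 libraries (edgeR 4.0.16 in R 4.3.3, robust, 10 residual degrees of freedom, median prior 5.69), so that all groups share one estimate of the spread, and the common biological coefficient of variation was 14.2%. The 9 comparisons were tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes tested, with an adjusted p under 0.05 taken as a call. The interaction is the effect of topp4-1 in pp1r3-2 minus its effect in wild type. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values were computed from TMM-scaled library sizes.

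The groups, tests, alternatives, gene lists and the rule for naming genes were set before the data were examined. The 25 gene lists hold 350 genes, of which 314 were tested: TOPP catalytic subunits, abscisic acid induced genes, abscisic acid receptors and kinases, salicylic acid defence, pattern-triggered early defence, NLR immune receptors, jasmonate response, ethylene and jasmonate defence, gibberellin feedback genes, gibberellin-induced and DELLA genes, early auxin response, auxin efflux carriers, shade and PIF response, wall loosening, photosynthesis, leaf senescence, heat shock, cold response factors, circadian clock, flavonoid and anthocyanin synthesis, aliphatic glucosinolate synthesis, stomatal lineage and guard cells, flower and meristem markers, flowering time and root markers. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. The root list had 2 tested members and received no list test. Each camera call is also given with the correlation estimated from the data; with it, of the calls of these 25 lists in the comparisons, 1 held, that of the TOPP list in topp-7m against pp1r3-2.

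Genes named in each comparison with wild type were taken from the 10 highest and 10 lowest fold changes among called genes with a mean of at least 5 CPM, a symbol, a nuclear protein-coding annotation and all 3 mutant libraries on the same side of all 3 wild-type libraries. In the other comparisons 5 and 5 were taken (for the interaction without the rule on sides). Up to 4 members per list with the smallest adjusted p, TOPP1 to TOPP9 and any gene with the symbol PP1R3 were added. Where there were more genes than the text can hold, they were taken in order of size. Genes at 0 to 3 counts in a group are given as counts or CPM. For AT2G05695 the bound sets 3 counts over the group in place of 0.

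Shared calls between comparisons with the same wild-type libraries are given beside the overlap of independent lists (the product of both numbers of calls divided by the genes tested) and beside 20 simulations of unchanged groups against the same controls. Alternatives were RLE size factors, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the compared libraries, the replicate number as a block, a log2 change of at least 1, an estimated correlation for lists, and leaving out each library. The counts of list members without wild-type replicate 3 and without double mutant replicate 3 were added after seeing that these libraries stood apart.

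Replicate numbers pair libraries only where same-numbered libraries of both genotypes deviate together from their group means at all 3 numbers, with r over 0.1. This held for pp1r3-2 and the double mutant, from values and not labels. A fit of their libraries with the number as a block, added after this was seen, was not checked on simulated data and its p-values are exploratory. The tests were checked on simulated data for 20037 genes. For pp1r3-2 against wild type edgeR recovered 40.3% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 6.54% of calls false. DESeq2 recovered 50.8%, 85.1% and 95.5%, with 19% of calls false. For the interaction edgeR recovered 15.7%, 59.0% and 83.3%, with 4.98% of calls false. With no change simulated, topp-7m against pp1r3-2 gave 1 call. A photosynthesis list changed in simulated topp4-1 was found by camera (adjusted p = 1.46e-102, and 6.41e-09 with an estimated correlation), and of 100 genes changed in both simulated pp1r3-2 and topp-7m 87 were recovered as shared. Sequence reads were not used here. The values of 1 of the list genes were left out and are not reported here.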

Results

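Transcript levels were measured by RNA-seq in leaves of Arabidopsis plants, 21 days after germination, in the Columbia background. The 5 genotypes were wild type, pp1r3-2, topp4-1, topp-7m and the double mutant pp1r3-2 topp4-1, with 3 libraries each. TOPP genes encode the catalytic subunits of the plant type 1 protein phosphatase, and PP1R3 is named in the series as a regulatory subunit of these enzymes. The total count per library was 18362312 to 19153778 in wild type, 17962200 to 20475286 in pp1r3-2, 18652357 to 20756997 in topp4-1, 18052020 to 19916914 in topp-7m and 18310335 to 19241457 in the double mutant. Of 33024 genes, 20037 had enough counts to be tested. The design asks how the pp1r3-2 and topp mutations relate to each other. Changes are log2 fold changes ± SE, and levels are CPM, counts scaled to library size, as mean ± SD with n = 3. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The labels do not say that the 3 libraries of a genotype came from separate plants, so p-values measure only the spread between these libraries, which may be technical. Coordinates refer to TAIR10.1.

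The TOPP genes were examined first, because the mutants are named for them. The labels call topp-7m a septuple topp mutant and do not name its 7 mutated genes. In this line 5 of the 9 TOPP transcripts fell. TOPP4 (AT2G39840, chromosome 2, 16627216 to 16629412) fell from 30.8 ± 1.83 CPM in wild type to 5.44 ± 0.342 CPM, a change of -2.50 ± 0.10 (adjusted p = 8.71e-10). AT4G11240 (symbol TOPP6 in the count table, chromosome 4, 6847112 to 6849317) fell from 44.5 ± 3.25 to 9.33 ± 0.495 CPM (-2.25 ± 0.10, adjusted p = 1.05e-09). AT5G43380 (symbol TOPP7 in the count table, chromosome 5, 17419790 to 17421982) was low everywhere and fell from 3.79 ± 0.955 to 1.1 ± 0.139 CPM (-1.78 ± 0.27, adjusted p = 0.000534). TOPP1 (AT2G29400, chromosome 2, 12613014 to 12615414) fell by 1.00 ± 0.11 on the log2 scale, from 130 ± 16.5 to 65.3 ± 6.97 CPM (adjusted p = 3.46e-05), and TOPP9 (AT3G05580) by 0.92 ± 0.14 (adjusted p = 0.000432). TOPP3 (AT1G64040) rose by 0.35 ± 0.09 (adjusted p = 0.0225). TOPP2, TOPP5 and TOPP8 did not pass the test in topp-7m, with 68.8 ± 5.98, 31.3 ± 1.87 and 43.9 ± 4.17 CPM against 68.6 ± 4.62, 32.7 ± 3.73 and 42.4 ± 0.91 CPM in wild type. The TOPP list as a whole fell in topp-7m (camera adjusted p = 2.75e-05, adjusted p = 0.194 with an estimated correlation), with 1 member up and 5 down, the same numbers when adjusted over the list alone. The TOPP3 call was lost without wild-type replicate 3 (adjusted p = 0.0905), without topp-7m replicate 2 (0.0916) or replicate 3 (0.0935), and when only the libraries compared were fitted (0.0671).

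In topp4-1 the TOPP4 transcript was present at 36.8 ± 1.90 CPM, against 30.8 ± 1.83 CPM in wild type and 30.6 ± 2.73 CPM in the double mutant. TOPP1 rose by 0.76 ± 0.11 (adjusted p = 3.05e-05), TOPP3 by 0.62 ± 0.09 (adjusted p = 4.34e-05), TOPP8 by 0.52 ± 0.09 (adjusted p = 0.000135) and TOPP4 by 0.26 ± 0.09 (adjusted p = 0.0224). The 4 rises among 9 TOPP genes were the same number when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0951, adjusted p = 0.253 with an estimated correlation). The TOPP4 call was lost without wild-type replicate 1 (adjusted p = 0.0788) or 3 (0.090), and without topp4-1 replicate 1 (0.10) or 2 (0.0717). In pp1r3-2, TOPP1 rose by 0.41 ± 0.11 (adjusted p = 0.0142) and AT5G43380 fell by 0.75 ± 0.25 (adjusted p = 0.0462). In the double mutant TOPP1 rose by 0.35 ± 0.11 (adjusted p = 0.0416). The TOPP1 call in pp1r3-2 was lost without wild-type replicate 3 (0.0735) or pp1r3-2 replicate 3 (0.0602). That in the double mutant was lost without wild-type replicate 1 (0.0552) or 3 (0.201), without double mutant replicate 2 (0.0666) or 3 (0.165), without a filter on low counts (0.0516) and in a fit of the compared libraries alone (0.117). The AT5G43380 call in pp1r3-2 was lost without wild-type replicate 2 (0.185) or 3 (0.123), without pp1r3-2 replicate 1 (0.0582), 2 (0.128) or 3 (0.115), without the filter (0.0607) and in a fit of the compared libraries alone (0.0858). No gene in the count table carried the symbol PP1R3, so the targeted gene of pp1r3-2 was not examined by name.

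**Figure D1:**
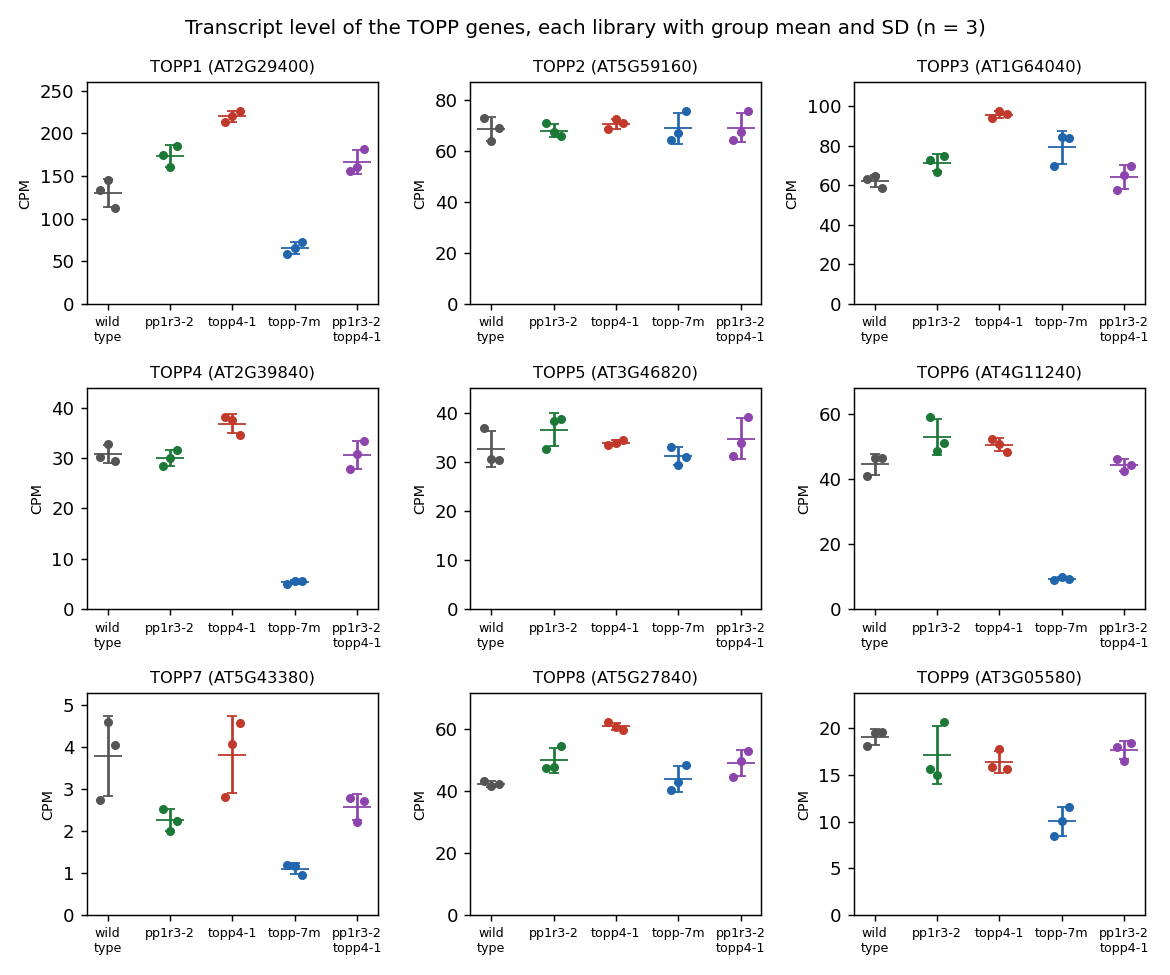
Transcript level of TOPP1 to TOPP9 in CPM (vertical axis, from 0, own scale per gene) in the 5 genotypes (horizontal axis); points are single libraries, lines the mean and bars the SD (n = 3). TOPP4 and AT4G11240 (TOPP6 in the count table) lay at 5.44 and 9.33 CPM in topp-7m and near wild-type levels in the other mutants.

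The comparison of pp1r3-2 with wild type asks how the leaf transcriptome of that line differs. The jasmonate-isoleucine hydroxylase gene CYP94B3 had 30.3 ± 11.4 CPM in wild type (365 to 796 counts per library) and 0 to 3 counts per library in pp1r3-2. Its relative CYP94C1 fell by 3.16 ± 0.21 (adjusted p = 2.36e-07). The gene with symbol ANS in the count table (AT2G38240) fell by 5.57 ± 0.31 (adjusted p = 8.05e-08), the transcription factor gene RAP2-6 by 4.22 ± 0.37 (adjusted p = 4.66e-06). The dehydrin gene XERO2 fell by 4.02 ± 0.21 (adjusted p = 3.56e-08), COR15A, which encodes a cold-induced chloroplast protein, by 3.92 ± 0.39 (adjusted p = 2.87e-05) and the jasmonate repressor gene JAZ10 by 3.51 ± 0.29 (adjusted p = 3.01e-06). The lipase gene LIP2 rose by 3.52 ± 0.69 (adjusted p = 0.00351; 4.24 without wild-type replicate 1), the phytochrome kinase substrate gene PKS4 by 2.33 ± 0.30 (adjusted p = 0.000107), the xylosidase gene BXL1 by 2.27 ± 0.16 (adjusted p = 4.40e-07). The linker histone gene HIS1-3 rose by 2.22 ± 0.34 (adjusted p = 0.000744) and the glutathione transferase gene GSTF3 by 2.21 ± 0.15 (adjusted p = 2.36e-07).

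By group, 16 of the 20 jasmonate response genes tested fell in pp1r3-2 and the other 4 did not pass (18 fell when adjusted over the list alone; median -1.71, camera adjusted p = 2.86e-12, adjusted p = 0.464 with an estimated correlation). Examples are JAZ5, listed as TIFY11A (-2.40 ± 0.25), and the jasmonate synthesis genes OPR3 (-1.85 ± 0.21) and AOC2 (-1.60 ± 0.18). Among NLR immune receptor genes 6 of 17 rose and 11 did not pass (7 adjusted over the list alone, camera adjusted p = 0.00535, adjusted p = 0.736 with an estimated correlation). AT5G66900 rose by 0.39 ± 0.09. Of 30 photosynthesis genes 8 rose and 22 did not pass (10 adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.736 with an estimated correlation). RCA, the Rubisco activase gene, was at 0.90 ± 0.16 and the light-harvesting genes AT1G29920 (symbol LHCB1.1) at 0.98 ± 0.17 and LHCB2.1 at 0.95 ± 0.17. A further gene with the symbol LHCB1.1, AT1G29910, did not pass (0.13 ± 0.16, adjusted p = 0.632). LHCB1 and LHCB2 genes are near-identical copies and uncertain singly. Wild-type replicate 3 held the highest chloroplast-encoded share of counts, 0.0813% against at most 0.0208% in the other libraries. Without it 3 NLR genes and 5 photosynthesis genes rose. The mean of the 4 flower and meristem markers tested, as a log2 difference from the wild-type mean, was at least 0.81 in each pp1r3-2 library and at most 0.41 in each wild-type library. Of these markers 1 was called and the list did not pass (camera adjusted p = 0.588).

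The remaining lists did not pass camera in pp1r3-2, although members moved. Among 28 abscisic acid induced genes 5 rose and 10 fell (5 and 11 adjusted over the list alone, camera adjusted p = 0.0849). RD29A fell by 2.90 ± 0.23, from 435 to 58.5 CPM, ERD10 by 2.77 ± 0.19 and COR47 by 1.79 ± 0.17. Of 28 salicylic acid defence genes 7 fell (8 adjusted over the list alone, camera adjusted p = 0.0695). Among them were the transporter gene EDS5, listed as DTX47 (-1.25 ± 0.20), and PR5 (-1.10 ± 0.24). Without wild-type replicate 3, 4 of them fell. In the 17-gene clock list 7 rose and 3 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.325), and the morning genes RVE1 (1.85 ± 0.12), CCA1 (1.46 ± 0.16) and RVE8 (1.09 ± 0.13) were among those that rose. The senescence regulator genes NAC92 (1.85 ± 0.21) and NAC029 (1.22 ± 0.22) rose, the gibberellin oxidase genes GA2OX2 (-1.39 ± 0.18) and GA2OX6 (-1.22 ± 0.19) fell, and the wall enzyme gene XTH22 rose by 1.38 ± 0.18. The median, mean and test differed in sign for the gibberellin feedback, early auxin response, auxin efflux, leaf senescence and clock lists.

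In all, 3862 genes were called in pp1r3-2 against wild type, 19.3% of those tested, 2193 higher and 1669 lower. The count was 2511 without wild-type replicate 2, 2388 without wild-type replicate 3 and 2472 without pp1r3-2 replicate 3. With a further requirement of a 2-fold change, 780 genes were called. The number of lists called was 3, and 5 without wild-type replicate 1, 6 without wild-type replicate 2 and 6 without pp1r3-2 replicate 2.

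**Figure D2:**
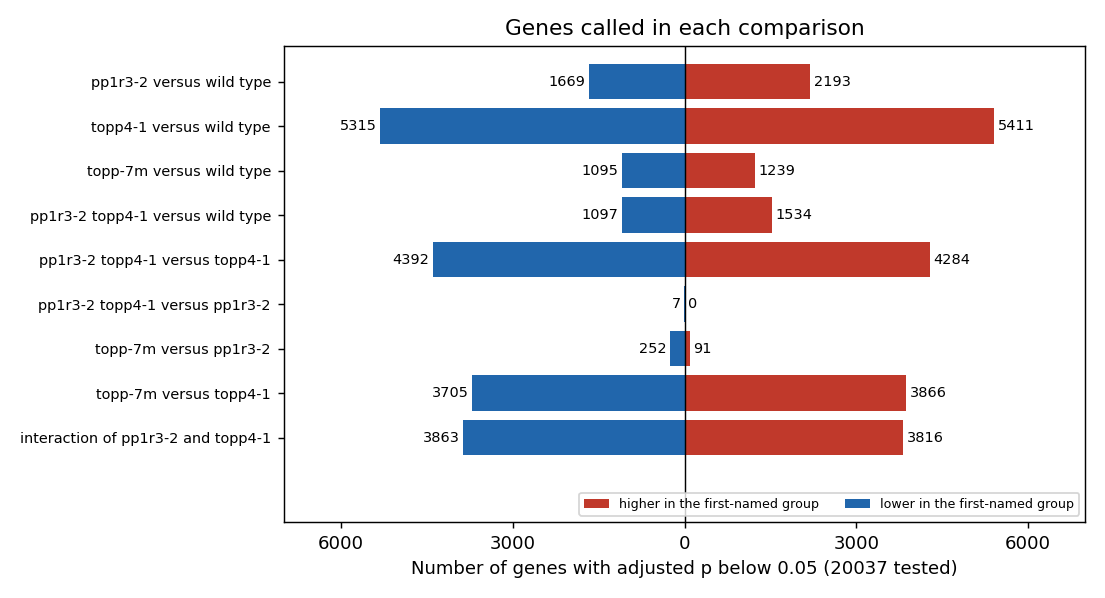
Number of genes with an adjusted p under 0.05 in each of the 9 comparisons (horizontal axis, counted outward from 0, 20037 genes tested), with genes higher in the first-named group to the right and lower to the left. The double mutant differed from topp4-1 at 8676 genes and from pp1r3-2 at 7.

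The comparison of topp4-1 with wild type asks how the line with this TOPP4 allele alone differs. It had the most called genes of the comparisons with wild type: 10726 genes, 53.5% of those tested, 5411 higher and 5315 lower. Plant defensin genes were among those that fell furthest: PDF1.2A (AT5G44420, chromosome 5, 17906968 to 17907638) went from 614 ± 254 to 2.23 ± 3.02 CPM, a change of -8.05 ± 1.07 (adjusted p = 8.64e-05). It had 7 to 125 counts per library in topp4-1. PDF1.2C changed by -8.44 ± 1.11 (adjusted p = 7.85e-05), PDF1.2B by -7.03 ± 0.96 (adjusted p = 0.000105) and PDF1.3 by -6.74 ± 0.80 (adjusted p = 3.22e-05). These near-identical genes share reads and their single values are uncertain. The acyltransferase gene ACT fell by 7.48 ± 0.99 (adjusted p = 6.40e-05) and the methionine sulfoxide reductase gene MSRB6 (AT4G04840) by 7.13 ± 0.42 (adjusted p = 1.78e-08). Without topp4-1 replicate 3 the change was -10.3 for PDF1.2A, -10 for PDF1.2C, -8.25 for PDF1.2B, -7.49 for PDF1.3 and -8.99 for ACT, and that of ACT was -6.70 without wild-type replicate 3. The glycosyltransferase gene UGT91C1 rose by 5.62 ± 0.40 (adjusted p = 1.01e-07), LIP2 by 5.55 ± 0.67 (adjusted p = 1.74e-05), the glycine-rich protein gene ATGRP9 (AT2G05440, chromosome 2, 1993038 to 1994177) by 5.01 ± 0.24 (adjusted p = 3.31e-09). The LIP2 change was 6.26 without wild-type replicate 1. HIPP22 rose by 4.72 ± 0.29 (adjusted p = 8.87e-09) and HIS1-3 by 4.59 ± 0.35 (adjusted p = 3.28e-07). The glucosidase gene BGLU30 rose by 4.34 ± 0.41, from 6.73 to 137 CPM, and the nitrilase gene NIT2 by 3.94 ± 0.27, from 97.2 to 1490 CPM.

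Beside the list changes in topp4-1, the flower and meristem mean was at least 1.72 in each topp4-1 library and at most 0.41 in each wild-type library. Photosynthesis genes fell in topp4-1 almost throughout: 28 of 30, the same number adjusted over the list alone (median -0.85, camera adjusted p = 3.17e-10, adjusted p = 0.411 with an estimated correlation). The Rubisco small subunit gene RBCS-2B fell by 1.97 ± 0.15, from 1362 to 348 CPM, and the photosystem I genes PSAD1 and PSAE1 by 1.06 ± 0.11 and 1.05 ± 0.11. RBCS genes are near-identical copies and uncertain singly. Of 13 senescence genes 11 rose (12 adjusted over the list alone, camera adjusted p = 0.000136, adjusted p = 0.341 with an estimated correlation). SEN1, listed as STR15, was at 2.51 ± 0.29 and NAC92 at 2.14 ± 0.21. Of 14 aliphatic glucosinolate synthesis genes 13 fell, also adjusted over the list alone (camera adjusted p = 5.45e-05, adjusted p = 0.431 with an estimated correlation). They included the regulator gene MYB28 (-2.21 ± 0.20) and the synthesis gene CYP79F1 (-2.55 ± 0.36). Of 11 stomatal genes 10 fell, likewise adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.253 with an estimated correlation). EPF2 was at -3.39 ± 0.51, SPCH at -2.59 ± 0.39 and MYB60 at -1.75 ± 0.23.

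Defence and hormone groups moved apart in topp4-1. Of 28 salicylic acid defence genes 18 rose and 3 fell (19 and 4 adjusted over the list alone, camera adjusted p = 0.000631, adjusted p = 0.431 with an estimated correlation). PR1 (AT2G14610) rose by 1.34 ± 0.16, from 3908 ± 308 to 9914 ± 545 CPM, and the regulator genes CBP60G and SARD1 by 1.38 ± 0.15 and 1.16 ± 0.13. Of 17 NLR genes 13 rose, also adjusted over the list alone (camera adjusted p = 0.000702, adjusted p = 0.431 with an estimated correlation). ADR1 was at 0.92 ± 0.11. Of 20 jasmonate genes 17 fell (18 adjusted over the list alone, camera adjusted p = 4.03e-07, adjusted p = 0.341 with an estimated correlation). The chlorophyllase gene CLH1 was at -4.49 ± 0.31 and AOC2 at -2.65 ± 0.19. Of the 4 auxin efflux carrier genes 3 fell, also adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.253 with an estimated correlation). PIN7 fell by 2.77 ± 0.19, from 74.9 ± 18.1 to 10.9 ± 3.07 CPM, PIN3 by 1.25 ± 0.12 and PIN4 by 0.97 ± 0.14. In the list of gibberellin-induced and DELLA genes 1 of 11 rose and 5 fell, as adjusted over the list alone (camera adjusted p = 0.0421, adjusted p = 0.341 with an estimated correlation). Those that fell included the DELLA genes RGL1 (-2.58 ± 0.27) and GAI (-0.67 ± 0.11), which encode repressors of the hormone response. In the clock list 8 of 17 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.0392, adjusted p = 0.431 with an estimated correlation). TOC1, listed as APRR1, rose by 0.68 ± 0.10 and RVE1 by 0.72 ± 0.11.

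Lists that did not pass camera in topp4-1 still held members that moved. Abscisic acid induced genes went both ways, 16 up and 9 down of 28 (17 and 9 adjusted over the list alone, camera adjusted p = 0.106): ATHB-7 rose by 3.16 ± 0.22, while RD29A fell by 3.95 ± 0.24 and ERD10 by 2.27 ± 0.19. Abscisic acid receptor and kinase genes also split, 3 up and 6 down of 12 (the same adjusted over the list alone, camera adjusted p = 0.462), with PYL7 at 1.17 ± 0.12 and PYL4 at -0.96 ± 0.09. Of 12 flavonoid genes 4 fell and 1 rose (camera adjusted p = 0.0716), with FLS1 at -3.81 ± 0.21, CHS at -2.88 ± 0.21 and the regulator MYB75 at 2.32 ± 0.40. Wall loosening genes, 3 up and 8 down of 16 (0.0515), included EXPA5 at -3.66 ± 0.24. Early auxin genes, 4 up and 9 down of 18 (5 and 9 adjusted over the list alone, 0.106), included IAA3, listed as SHY2, at -3.05 ± 0.24 and GH3.5 at 2.38 ± 0.17. Ethylene and jasmonate defence genes, 1 up and 4 down of 7 (0.0951), included ORA59, listed as ERF094, at -2.91 ± 0.28 and ERF1B at 1.74 ± 0.20. Gibberellin feedback genes were 5 up and 1 down of 7 (0.0694), with GID1C at 0.76 ± 0.09. Heat shock genes all fell, 5 of 5 (0.0712), but 2 fell without wild-type replicate 3. Pattern-triggered early defence genes were 3 up and 2 down of 14 (3 up and none down adjusted over the list alone, 0.471), with WRKY33 at 0.69 ± 0.16, and shade genes 2 up and 4 down of 8 (0.471). Of the markers of other organs and states, 3 of 4 flower and meristem genes rose (0.0716), with PI at 4.48 ± 0.58, 2 of 4 cold response factors rose (3 adjusted over the list alone, 0.316), 1 of 3 flowering time genes rose (SOC1, 0.53 ± 0.11; 0.509), and the 2 root markers with enough counts were too few for a list test and neither was called. The bracketed p-values of lists given without a name are camera adjusted p-values, and each list without further counts had the same counts when adjusted over the list alone.

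Leaving out any wild-type or topp4-1 library gave a count of called genes in topp4-1 between 9237 and 10191. Of the called genes 3821 changed at least 2-fold, 1572 higher and 2249 lower. The genes GA2OX8, THI2.1, JMT, SAUR22 and ATXTH17 were at or near 0 counts in topp4-1 and no fold is given for them. GA20OX3 had 19 to 46 counts per library in topp4-1 and 0 to 3 in wild type.

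**Figure D3:**
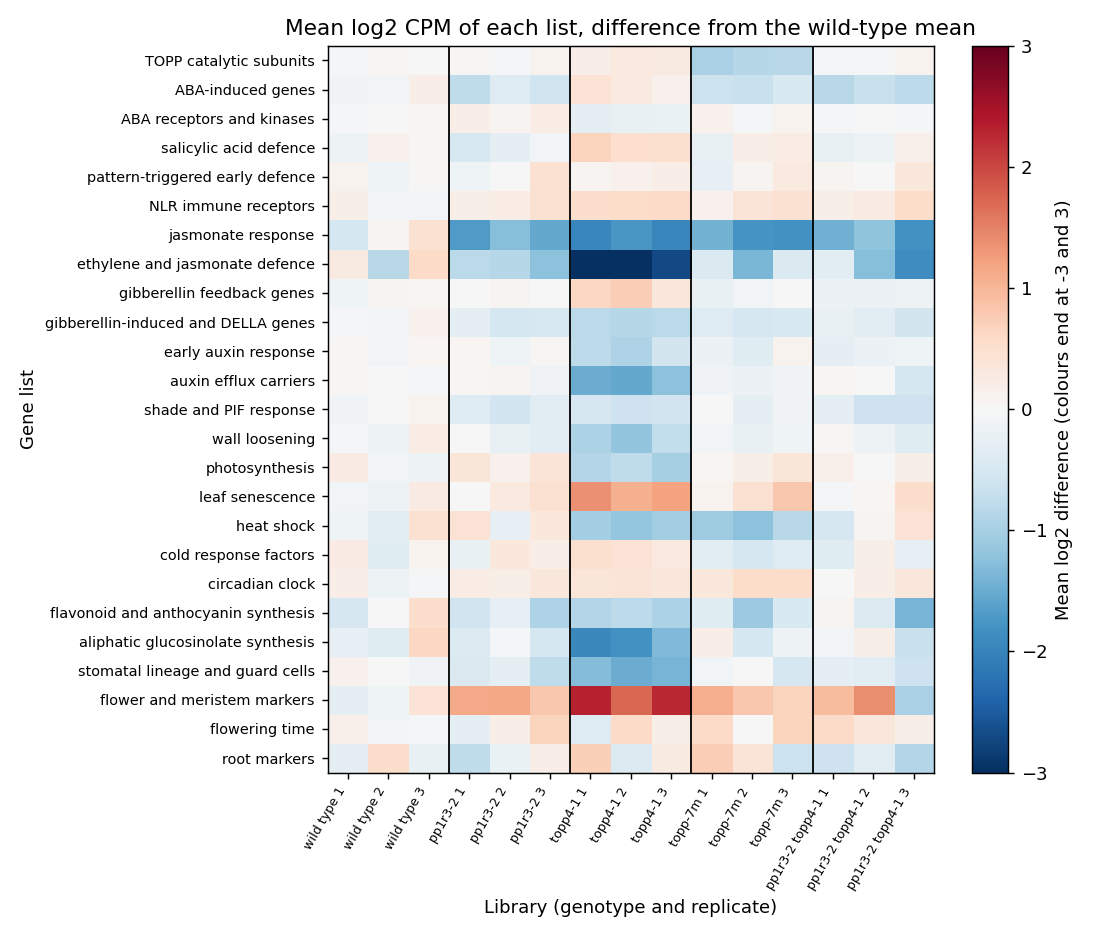
Mean log2 CPM of each of the 25 gene lists (vertical axis) in each of the 15 libraries (horizontal axis, grouped by genotype), as the difference from the wild-type mean, with red higher, blue lower and colours ending at -3 and 3. Jasmonate response genes were lower in all 4 mutants, and in topp4-1 senescence genes were higher and photosynthesis, glucosinolate and stomatal genes lower.

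Setting the double mutant against topp4-1 asks what pp1r3-2 does to plants that carry topp4-1. Several genes that topp4-1 had moved far in wild type differed here in the other direction. ATGRP9 was at 724 ± 122 CPM in topp4-1 and 12.4 CPM in the double mutant (-5.87 ± 0.25, adjusted p = 4.45e-09), BGLU30 at 137 and 3.09 CPM (-5.47 ± 0.44, adjusted p = 1.39e-06), and the laccase gene LAC7 fell by 5.73 ± 0.71 (adjusted p = 2.57e-05). PDF1.2C was higher by 6.33 ± 1.09 (adjusted p = 0.000767), PDF1.2A by 6.30 ± 1.02 (adjusted p = 0.000478), MSRB6 by 5.66 ± 0.44 (adjusted p = 3.13e-07) and PDF1.3 by 5.53 ± 0.77 (adjusted p = 0.000142). The LAC7 change was -7.34 without double mutant replicate 3. Without topp4-1 replicate 3 PDF1.2C was at 7.89, PDF1.2A at 8.54 and PDF1.3 at 6.27, and without double mutant replicate 1 PDF1.2C and PDF1.2A were at 5.33 each. Among TOPP genes TOPP3 fell by 0.58 ± 0.09 (adjusted p = 0.000116), TOPP1 by 0.41 ± 0.11 (adjusted p = 0.00644), TOPP8 by 0.31 ± 0.09 (adjusted p = 0.00894) and TOPP4 by 0.26 ± 0.09 (adjusted p = 0.0239). The TOPP8 call was lost without double mutant replicate 1 (0.053). That of TOPP4 was lost without topp4-1 replicate 1 (0.0997) or 2 (0.0623), without double mutant replicate 1 (0.121) or 2 (0.0579) and in a fit of the compared libraries alone (0.0719).

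All 30 photosynthesis genes tested were higher in the double mutant than in topp4-1, also adjusted over the list alone (camera adjusted p = 1.52e-14, adjusted p = 0.339 with an estimated correlation), RBCS-2B by 2.23 ± 0.15. The flower and meristem mean was at least 1.72 in each topp4-1 library and ran from -0.97 to 1.40 over those of the double mutant. Of 28 salicylic acid genes 19 fell and 1 rose, as adjusted over the list alone (camera adjusted p = 5.84e-05, adjusted p = 0.381 with an estimated correlation). PR1 fell by 1.53 ± 0.16 and PR2, listed as BGL2, by 1.76 ± 0.18. Of 28 abscisic acid induced genes 19 fell and 1 rose, as adjusted over the list alone (camera adjusted p = 1.47e-05, adjusted p = 0.339 with an estimated correlation). ATHB-7 fell by 2.70 ± 0.22, while RD22 rose by 1.60 ± 0.19. Glucosinolate genes rose, 12 of 14 (13 adjusted over the list alone, camera adjusted p = 4.32e-05, adjusted p = 0.381 with an estimated correlation), MYB28 by 2.25 ± 0.20. Stomatal genes rose, 8 of 11 (9 adjusted over the list alone, camera adjusted p = 0.00384, adjusted p = 0.223 with an estimated correlation). MYB60 rose by 1.45 ± 0.23 and SPCH by 1.67 ± 0.40. Senescence genes fell, 10 of 13, also adjusted over the list alone (camera adjusted p = 0.00030, adjusted p = 0.348 with an estimated correlation), SEN1 by 2.13 ± 0.28. Of 4 auxin efflux genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.00939, adjusted p = 0.223 with an estimated correlation). PIN7 rose by 2.37 ± 0.19 and PIN3 by 1.72 ± 0.12. Wall loosening genes were 8 up and 2 down of 16 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.348 with an estimated correlation), EXPA5 up by 2.71 ± 0.24. Without double mutant replicate 3, 1 fell. Of 20 jasmonate genes 7 rose and 1 fell, as adjusted over the list alone, and the list did not pass (camera adjusted p = 0.094). The median, mean and test differed in sign for the pattern-triggered defence and flowering time lists. In all 8676 genes were called, 43.3% of those tested, 4284 higher and 4392 lower in the double mutant, and 2829 of them changed at least 2-fold.

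Setting the double mutant against pp1r3-2 asks what topp4-1 does to plants that carry pp1r3-2. Here 7 genes were called, all lower in the double mutant, and no TOPP gene or other list member was among them. ARP9, an actin-related protein gene (AT5G43500, chromosome 5, 17469490 to 17473619), fell by 1.24 ± 0.10 (adjusted p = 3.29e-05), from 36.5 to 15.5 CPM. It had 18.5 CPM in wild type, 17.7 in topp4-1 and 16.8 in topp-7m. ARR5, a cytokinin-induced response regulator gene (AT3G48100), fell by 0.85 ± 0.12 (adjusted p = 0.0101), from 30.6 to 16.9 CPM, with 14.7 CPM in wild type. The call was lost without pp1r3-2 replicate 1 (0.095) and in a fit of the compared libraries alone (0.347). The other 5, without a symbol, were chosen after their values were seen. An unannotated locus (chromosome 5, 14088074 to 14090094) had 21 to 47 counts per library in the double mutant, 301 to 359 in pp1r3-2 and 176 to 238 in wild type (-3.25 ± 0.19, adjusted p = 2.28e-07). AT2G05695 (chromosome 2, 5009533 to 5009872) had 56 to 63 counts per library in pp1r3-2, 0 in the double mutant, wild type and topp-7m and 0 to 1 in topp4-1. It was at least 56.4-fold lower in the double mutant with a floor of 3 counts over the group. AT3G05945 changed by -1.38 ± 0.20 (adjusted p = 0.0137), AT3G19680 by -0.70 ± 0.11 (adjusted p = 0.0465) and AT4G27450 by -0.64 ± 0.10 (adjusted p = 0.0465).

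Same-numbered libraries of pp1r3-2 and the double mutant deviated together at all 3 numbers (r = 0.256, 0.217 and 0.447). With the replicate number as a block in a fit of these libraries alone, chosen after this was seen, 103 genes were called, 10 higher and 93 lower. All 7 were among them, and topp4-1 in wild type had moved 65 of the 103 the opposite way and 13 the same way. They included, named after their values were seen, BXL2 (-1.11, adjusted p = 0.000266), BGAL4 (-1.07, adjusted p = 0.000153), STP1 (-0.78, adjusted p = 0.00254) and ALD1 (0.87, adjusted p = 0.018). With this block the aliphatic glucosinolate list was called beside the 3 below (camera adjusted p = 0.0351, adjusted p = 0.803 with an estimated correlation), while its adjusted p was 0.249 without a block and 0.275 with a block in the fit of all libraries. Without a block, over both directions, 1377 genes had an unadjusted p under 0.05, and DESeq2 called 59 genes, 9 higher and 50 lower. The count of 7 was 2 without pp1r3-2 replicate 1, 4 without double mutant replicate 2 and 12 without double mutant replicate 3. Camera called 3 lists whose members were not called singly without the block. Abscisic acid receptor and kinase genes were lower as a list (median -0.21, adjusted p = 0.00491, adjusted p = 0.702 with an estimated correlation), with 1 member past the threshold adjusted over the list alone. Photosynthesis genes were lower (median -0.21, adjusted p = 3.12e-05, adjusted p = 0.818 with an estimated correlation) and salicylic acid defence genes higher (median 0.19, adjusted p = 9.61e-05, adjusted p = 0.818 with an estimated correlation), with no member of either past it adjusted over the list alone. The number of lists called was 5 without pp1r3-2 replicate 1, 5 without pp1r3-2 replicate 3 and 7 without double mutant replicate 3. That library lay apart from the other double mutant libraries on the second principal component of all genes, at -62.7 against -4.60 and -6.26. The median, mean and test differed in sign for the pattern-triggered defence, senescence and heat shock lists.

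The interaction asks directly whether the effect of topp4-1 differs between the wild-type and the pp1r3-2 background. It was called for 7679 genes, 38.3% of those tested, 3816 positive and 3863 negative. The named genes with the largest interaction had each been moved by topp4-1 in wild type in the direction opposite to their interaction: PDF1.2C (8.72 ± 1.33, adjusted p = 0.000432), PDF1.2A (8.22 ± 1.27, adjusted p = 0.00049), ACT (7.33 ± 1.22, adjusted p = 0.000658), PDF1.2B (7.02 ± 1.19, adjusted p = 0.000854) and MSRB6 (6.77 ± 0.52, adjusted p = 5.94e-07) on the positive side. On the negative side were LIP2 (-6.14 ± 0.87, adjusted p = 0.000131), UGT91C1 (-5.97 ± 0.54, adjusted p = 2.40e-06), HIS1-3 (-5.10 ± 0.46, adjusted p = 3.97e-06), BGLU30 (-4.90 ± 0.62, adjusted p = 7.43e-05) and LAC7 (-4.89 ± 1.04, adjusted p = 0.00245). Without topp4-1 replicate 3 PDF1.2C was at 10.29, PDF1.2A at 10.47, ACT at 8.85 and PDF1.2B at 8.25, and without double mutant replicate 1 PDF1.2C was at 7.71, PDF1.2A at 7.25 and PDF1.2B at 6.2. ACT was at 6.55 without wild-type replicate 3. LAC7 was at -3.88 without pp1r3-2 replicate 3, -6.50 without double mutant replicate 3 and -5.56 without wild-type replicate 3, and LIP2 at -7.01 without double mutant replicate 3 and -6.85 without wild-type replicate 1. TOPP1 (-0.82 ± 0.15, adjusted p = 0.000614), TOPP3 (-0.77 ± 0.13, adjusted p = 0.000267), TOPP8 (-0.55 ± 0.12) and AT4G11240 (-0.44 ± 0.12, adjusted p = 0.0101) also passed, and TOPP4 did not (-0.23 ± 0.12, adjusted p = 0.166). Of the 1572 genes that topp4-1 raised at least 2-fold in wild type, with a median of 1.66, the median change by topp4-1 in pp1r3-2 was -0.06 (quartiles -0.32 to 0.19), 1263 of them (80.3%) passed the interaction test. In the pp1r3-2 background 2 of them were called, ARR5 (-0.85) and AT4G27450 (-0.64), both lower and so opposite to topp4-1 in wild type. Of the 2249 lowered genes, with a median of -1.57, the median in pp1r3-2 was 0.02 (quartiles -0.15 to 0.18) and 1777 (79.0%) passed the interaction test. None was called in the pp1r3-2 background by edgeR without a block. With the replicate block in a fit of the pp1r3-2 and double mutant libraries alone, 8 of the lowered genes were called, 5 lower and 3 higher, and 43 of the raised genes, 42 lower and 1 higher. Among those lowered by topp4-1 in wild type and lower here too were RD29A (-0.60, adjusted p = 0.00512) and ERD10 (-0.39, adjusted p = 0.0407), which were picked after their values were seen. Across all genes tested, which are not independent replicates, the effects in the 2 backgrounds had r = -0.083 and a slope of -0.026.

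**Figure D4:**
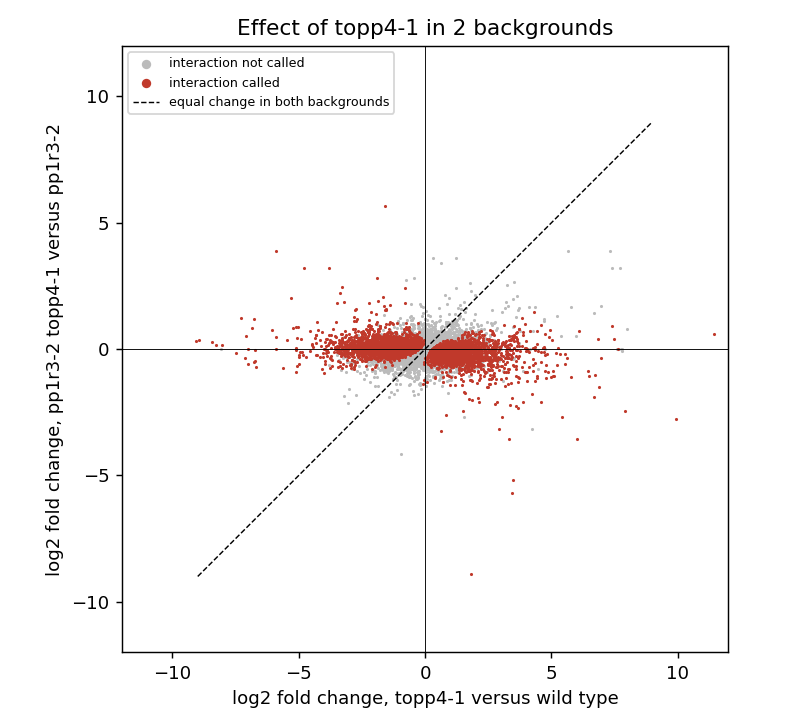
Each point is a gene, with its log2 fold change by topp4-1 in the wild-type background (horizontal axis) and in the pp1r3-2 background (vertical axis), red where the interaction was called and grey where it was not; the dashed line marks equal change. Points spread along the horizontal axis and not along the dashed line, with a slope of -0.026 over all genes.

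The interaction was called for 13 lists. Positive, against the direction in topp4-1 alone, were jasmonate genes (16 of 20, also adjusted over the list alone; median 2.14, camera adjusted p = 4.94e-07, adjusted p = 0.298 with an estimated correlation). CLH1 was at 4.64 ± 0.40 and AOC2 at 2.65 ± 0.26. Also positive were photosynthesis genes (20 of 30, 22 adjusted over the list alone, camera adjusted p = 4.94e-07, adjusted p = 0.508 with an estimated correlation), with RBCS-2B at 2.13 ± 0.21. Glucosinolate genes were positive (12 of 14, 14 adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.453 with an estimated correlation), with MYB28 at 2.37 ± 0.27. So were stomatal genes (7 of 11, camera adjusted p = 0.00223, adjusted p = 0.281 with an estimated correlation), with SPCH at 2.91 ± 0.53. The same held for auxin efflux genes (3 of 4, camera adjusted p = 0.0265, adjusted p = 0.281 with an estimated correlation), with PIN7 at 2.91 ± 0.25, and gibberellin-induced and DELLA genes (6 of 11, camera adjusted p = 0.0318, adjusted p = 0.281 with an estimated correlation), with RGL1 at 2.67 ± 0.36. Wall loosening genes (7 positive and 2 negative of 16, camera adjusted p = 0.0318, adjusted p = 0.437 with an estimated correlation) included EXPA5 at 3.86 ± 0.32, and flavonoid genes (4 and 1 of 12, camera adjusted p = 0.0446, adjusted p = 0.508 with an estimated correlation) FLS1 at 4.06 ± 0.27. Negative were senescence genes (10 of 13, 11 adjusted over the list alone, camera adjusted p = 0.000222, adjusted p = 0.37 with an estimated correlation), with SEN1 at -3.11 ± 0.40. So were NLR genes (10 of 17, 11 adjusted over the list alone, camera adjusted p = 0.0054, adjusted p = 0.508 with an estimated correlation), and salicylic acid genes (13 negative and 2 positive of 28, also adjusted over the list alone, camera adjusted p = 0.0273, adjusted p = 0.551 with an estimated correlation), with PR1 at -1.04 ± 0.22. Gibberellin feedback genes (4 of 7, camera adjusted p = 0.0281, adjusted p = 0.281 with an estimated correlation) and clock genes (7 negative and 1 positive of 17, camera adjusted p = 0.0318, adjusted p = 0.508 with an estimated correlation) were negative too, with GID1C at -0.84 ± 0.12 and RVE1 at -0.99 ± 0.16. Where no second count is given, the count adjusted over the list alone was the same. Without double mutant replicate 1, 8 lists were called.

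Compared with wild type, the double mutant again had lower jasmonate transcripts. CYP94B3 had 0 to 2 counts per library, RAP2-6 fell by 5.16 ± 0.40 (adjusted p = 1.93e-06), ANS (AT2G38240) by 4.76 ± 0.29 (adjusted p = 1.96e-07), XERO2 by 4.35 ± 0.21 (adjusted p = 2.11e-08) and the jasmonate sulfotransferase gene SOT15 by 4.12 ± 0.64. RD29A fell by 3.49 ± 0.24, from 435 to 38.7 CPM. LIP2 rose by 2.93 ± 0.71 (adjusted p = 0.0167), the squalene epoxidase gene SQE5 by 2.48 ± 0.30 (adjusted p = 0.000116) and PKS4 by 1.96 ± 0.30. The LIP2 call was lost without wild-type replicate 2 (0.0745) or 3 (0.075) and without double mutant replicate 3 (0.0782, with a change of 2.06), and its change was 3.65 without wild-type replicate 1. SOT15 was at -5.02 without double mutant replicate 1. Of 20 jasmonate genes 16 fell (17 adjusted over the list alone, camera adjusted p = 8.04e-14, adjusted p = 0.345 with an estimated correlation). OPR3 fell by 1.82 ± 0.21 and AOC2 by 1.60 ± 0.18. Of 17 NLR genes 7 rose (10 adjusted over the list alone, camera adjusted p = 9.66e-05, adjusted p = 0.955 with an estimated correlation). AT5G66900 rose by 0.49 ± 0.09. Without wild-type replicate 3, and likewise without double mutant replicate 3, 3 NLR genes rose. The flower and meristem mean ran from -0.97 to 1.40 over the double mutant libraries, 1 marker, PI, was called and the list did not pass (camera adjusted p = 0.687). The PI call was lost without double mutant replicate 3 (adjusted p = 0.106). Of 28 abscisic acid induced genes 3 rose and 8 fell (4 and 10 adjusted over the list alone, camera adjusted p = 0.0183, direction down, adjusted p = 0.955 with an estimated correlation). The median was 0.0045 and the mean -0.74, so the call rests on the genes that fell.

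Outside the called lists, the clock genes RVE1 (1.59 ± 0.11), CCA1 (1.38 ± 0.16) and LHY (1.11 ± 0.15) rose in the double mutant, as did RCA (0.93 ± 0.16), 1 of 3 photosynthesis genes that rose, also 3 adjusted over the list alone (camera adjusted p = 0.477). The median, mean and test also differed in sign for the abscisic acid receptor, auxin efflux, senescence, cold and clock lists. In all 2631 genes were called against wild type, 13.1% of those tested, 1534 higher and 1097 lower, 546 of them by at least 2-fold. The count was 1596 without wild-type replicate 2, 1379 without wild-type replicate 3, 1438 without double mutant replicate 3 and 1342 in a fit of the compared libraries alone. The 3 lists called became 5 without wild-type replicate 1.

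The comparison of topp-7m with wild type asks how the leaf transcriptome of the septuple line differs. Beyond the TOPP genes, RAP2-6 fell by 5.49 ± 0.41 (adjusted p = 1.63e-06), ANS (AT2G38240) by 4.86 ± 0.29 (adjusted p = 1.33e-07), COR15A by 4.12 ± 0.39 (adjusted p = 3.34e-05), XERO2 by 3.68 ± 0.20 (adjusted p = 3.84e-08) and RD29A by 3.46 ± 0.24 (adjusted p = 8.94e-07). The RAP2-6 change was -6.59 without topp-7m replicate 2. CYP94B3 had 1 to 3 counts per library. UGT91C1 rose by 2.83 ± 0.41 (adjusted p = 0.000624), LIP2 by 2.54 ± 0.73 (adjusted p = 0.0394), HIPP22 by 2.31 ± 0.29 (adjusted p = 0.000124), the serine-rich protein gene SIS by 2.1 ± 0.23 (adjusted p = 7.22e-05) and GSTF3 by 2.09 ± 0.15 (adjusted p = 4.98e-07). The LIP2 call was lost without wild-type replicate 2 (0.137) or 3 (0.131), without topp-7m replicate 2 (0.156, with a change of 1.79) or 3 (0.0572) and without the filter on low counts (0.0711), and its change was 3.26 without wild-type replicate 1.

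Of 20 jasmonate genes 17 fell in topp-7m, also adjusted over the list alone (median -2.0, camera adjusted p = 1.95e-17, adjusted p = 0.185 with an estimated correlation). OPR3 was at -2.04 ± 0.21 and AOC2 at -1.83 ± 0.19. Photosynthesis genes were 8 up and 2 down of 30 (10 and 2 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.764 with an estimated correlation): AT1G29920 (symbol LHCB1.1) rose by 1.18 ± 0.17, LHCB2.1 by 1.17 ± 0.18 and AT1G29910, with the symbol LHCB1.1 too, by 0.52 ± 0.16 (adjusted p = 0.0492). By contrast RBCS-2B fell by 0.99 ± 0.15, from 1362 to 685 CPM, and RBCS-1B by 0.84 ± 0.16. Of 17 NLR genes 5 rose (11 adjusted over the list alone, camera adjusted p = 5.79e-05, adjusted p = 0.561 with an estimated correlation). ADR1 rose by 0.47 ± 0.11. The flower and meristem mean was 0.66 to 1.09 per library, no marker was called by edgeR and the list did not pass (camera adjusted p = 0.579). Of 17 clock genes 8 rose and 1 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.000313, adjusted p = 0.485 with an estimated correlation). RVE1 rose by 1.17 ± 0.11 and LNK1 by 1.16 ± 0.14. Of 13 senescence genes 3 rose (4 adjusted over the list alone, camera adjusted p = 0.00231, adjusted p = 0.561 with an estimated correlation): NAC92 by 1.63 ± 0.20, SEN1 by 1.44 ± 0.28 and NAC029 by 1.25 ± 0.22. Flavonoid genes fell, 2 of 12, also adjusted over the list alone (camera adjusted p = 0.00508, adjusted p = 0.561 with an estimated correlation), CHI1 by 0.61 ± 0.12. Gibberellin-induced and DELLA genes fell, 4 of 11 (4, and 1 up, adjusted over the list alone, camera adjusted p = 0.0329, adjusted p = 0.286 with an estimated correlation), GA2OX6 by 1.34 ± 0.19. Heat shock genes fell, 2 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0052, adjusted p = 0.404 with an estimated correlation): HSFA2 by 2.24 ± 0.54 (adjusted p = 0.0159) and CLPB1 by 0.54 ± 0.16 (adjusted p = 0.0384).

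HSFA2 was lost without wild-type replicate 3 (0.0628) or topp-7m replicate 1 (0.0522), 2 (0.0651) or 3 (0.0537). CLPB1 was lost without wild-type replicate 1 (0.0748), 2 (0.0748) or 3 (0.0719) or topp-7m replicate 1 (0.107) or 2 (0.132). Without wild-type replicate 3, 2 NLR genes and 5 photosynthesis genes rose, and 1 gibberellin-induced gene and 1 flavonoid gene fell. Abscisic acid induced genes were 4 up and 10 down of 28 (8 and 11 adjusted over the list alone) and did not pass (camera adjusted p = 0.0508, direction down, with a median of 0.14 and a mean of -0.59). The median, mean and test also differed in sign for the shade list. In all 2334 genes were called in topp-7m, 11.7% of those tested, 1239 higher and 1095 lower, 517 of them by at least 2-fold. The count was 1455 without wild-type replicate 2, 1349 without wild-type replicate 3 and 1397 without topp-7m replicate 3.

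Setting topp-7m against pp1r3-2 asks how these lines differ from each other. TOPP genes fell, 4 of 9 (5 adjusted over the list alone, camera adjusted p = 8.84e-11, adjusted p = 0.0408 with an estimated correlation): AT4G11240 by 2.50 ± 0.10 (adjusted p = 4.37e-10), TOPP4 by 2.46 ± 0.10 (adjusted p = 5.49e-10), TOPP1 by 1.41 ± 0.11 (adjusted p = 5.25e-06) and TOPP9 by 0.77 ± 0.14 (adjusted p = 0.00898). Salicylic acid defence genes were higher in topp-7m, 3 of 28 (10 adjusted over the list alone, camera adjusted p = 2.29e-06, adjusted p = 0.619 with an estimated correlation): PR5 by 1.52 ± 0.24, from 582 to 1665 CPM, PR2 by 1.13 ± 0.18, from 787 to 1725 CPM, and PR1 by 0.79 ± 0.16 (adjusted p = 0.0182). Heat shock genes were lower, 3 of 5 (4 adjusted over the list alone, camera adjusted p = 0.000252, adjusted p = 0.271 with an estimated correlation): HSFA2 by 2.46 ± 0.54 (adjusted p = 0.0369), MED37C by 1.84 ± 0.37 (adjusted p = 0.0242) and HSP90-1 by 1.69 ± 0.33 (adjusted p = 0.0242). ATGRP9 rose by 2.25 ± 0.23 (adjusted p = 0.000158), the amylase gene AMY1 by 1.90 ± 0.26 (adjusted p = 0.00284) and PORA, which acts in chlorophyll synthesis, by 1.56 ± 0.27 (adjusted p = 0.00881). RBCS-2B fell by 1.09 ± 0.15 (adjusted p = 0.00238) and RVE1 by 0.68 ± 0.11 (adjusted p = 0.0068).

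Several of these calls depended on which libraries were included. Without pp1r3-2 replicate 1 or 3, or topp-7m replicate 1, 2 or 3, the adjusted p of HSFA2 was 0.124, 0.0902, 0.134, 0.164 and 0.0825. Without the first 4 of these that of MED37C was 0.0845, 0.073, 0.102 and 0.128, and that of HSP90-1 0.0837, 0.0771, 0.109 and 0.119. PR1 was lost without pp1r3-2 replicate 3 (0.0534), without topp-7m replicate 2 (0.068) and in a fit of the compared libraries alone (0.088). TOPP9 and PORA were lost without topp-7m replicate 2 (0.0503 each), and TOPP9 also in the fit of the compared libraries alone (0.083). In all 343 genes were called, 91 higher and 252 lower in topp-7m, 70 of them by at least 2-fold. An unadjusted p under 0.05 was found for 2753 genes, and DESeq2 called 799. The count was 163 without pp1r3-2 replicate 1, 178 without pp1r3-2 replicate 3, 159 without topp-7m replicate 1, 76 without topp-7m replicate 2 and 160 in a fit of the compared libraries alone. The 3 lists called became 5 without pp1r3-2 replicate 3, 7 without topp-7m replicate 1 and 5 without topp-7m replicate 3. The median, mean and test differed in sign for the abscisic acid induced, NLR, pattern-triggered defence, gibberellin-induced and flowering time lists.

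Setting topp-7m against topp4-1 asks how the line with several lowered TOPP transcripts differs from the line with the TOPP4 allele. Of 9 TOPP genes 7 were lower in topp-7m, also adjusted over the list alone (camera adjusted p = 7.46e-06, adjusted p = 0.107 with an estimated correlation), TOPP4 by 2.76 ± 0.10 (adjusted p = 1.96e-10) and TOPP1 by 1.75 ± 0.11 (adjusted p = 5.66e-08). PDF1.2C was higher by 6.75 ± 1.09 (adjusted p = 0.00069), PDF1.2A by 6.50 ± 1.02 (adjusted p = 0.000575) and MSRB6 by 5.72 ± 0.44 (adjusted p = 6.42e-07), while LAC7 fell by 5.34 ± 0.68 (adjusted p = 5.99e-05) and ATGRP9 by 3.96 ± 0.23 (adjusted p = 5.66e-08). Without topp4-1 replicate 3 PDF1.2C was at 8.31 and PDF1.2A at 8.74. The flower and meristem mean was 0.66 to 1.09 per library in topp-7m and at least 1.72 in topp4-1. All 30 photosynthesis genes rose (camera adjusted p = 6.75e-19, adjusted p = 0.241 with an estimated correlation), LHCB6 by 1.55 ± 0.13. Glucosinolate genes rose, 13 of 14 (camera adjusted p = 7.46e-06, adjusted p = 0.296 with an estimated correlation), MYB28 by 2.13 ± 0.20. Stomatal genes rose, 9 of 11 (camera adjusted p = 0.000244, adjusted p = 0.107 with an estimated correlation), EPF2 by 3.01 ± 0.51. These counts were the same when adjusted over the list alone. Auxin efflux genes rose, 3 of 4 (camera adjusted p = 0.00318, adjusted p = 0.107 with an estimated correlation), PIN7 by 2.44 ± 0.19, and wall loosening genes were 9 up and 3 down of 16 (camera adjusted p = 0.0191, adjusted p = 0.296 with an estimated correlation), EXPA5 up by 2.58 ± 0.24, again the same adjusted over the list alone.

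Lower in topp-7m than in topp4-1 were abscisic acid induced genes (17 down and 1 up of 28, as adjusted over the list alone, camera adjusted p = 3.75e-05, adjusted p = 0.241 with an estimated correlation), ATHB-7 by -2.41 ± 0.22, and salicylic acid genes (15 down and 2 up of 28, 18 and 3 adjusted over the list alone, camera adjusted p = 0.000112, adjusted p = 0.379 with an estimated correlation), PR1 by -1.05 ± 0.16. Senescence genes were lower, 9 of 13 (11 adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.296 with an estimated correlation), SEN1 by -1.07 ± 0.28. Gibberellin feedback genes were 4 down and 1 up of 7, as adjusted over the list alone (camera adjusted p = 0.0401, adjusted p = 0.241 with an estimated correlation), with SCL3 at -0.75 ± 0.09 and GA3OX1 at 1.40 ± 0.27. In all 7571 genes were called, 37.8% of those tested, 3866 higher and 3705 lower, and 2398 changed at least 2-fold.

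Finally, the calls against wild type were compared between mutants, which asks how far the lines change the same genes. Between pp1r3-2 and topp-7m, 1685 genes were called in the same direction, 922 higher and 763 lower, with 4 in opposite directions. Independent lists of these sizes would share 135.6 and 91.2. Jasmonate genes such as AOC2, OPR3 and JAZ10 and the dehydrin gene ERD10 were among the shared falls. Between pp1r3-2 and topp4-1, 2504 were shared (1392 higher and 1112 lower; 322 opposite; 592.2 and 442.7 from independent lists), and between topp4-1 and topp-7m 1950 (1034 and 916; 48 opposite; 334.6 and 290.5). Between topp4-1 and the double mutant 1709 were shared (908 and 801; 259 opposite; 414.3 and 291), and between pp1r3-2 and the double mutant 2134 (1242 and 892; 1 opposite; 167.9 and 91.4). Simulated unchanged groups set against the same controls shared at most 1 call in 20 simulations. The covariance of log2 fold changes was 0.23 for pp1r3-2 and topp-7m against 0.0439 in the simulations, 0.32 for pp1r3-2 and topp4-1 against 0.0441, 0.329 for topp4-1 and topp-7m against 0.0441, 0.290 for topp4-1 and the double mutant against 0.0439, and 0.267 for pp1r3-2 and the double mutant against 0.0438. The matching correlations across genes, which are not independent replicates, were 0.760, 0.513, 0.596, 0.505 and 0.837, against simulated values of 0.498, 0.506, 0.51, 0.503 and 0.497. Part of the excess may come from shared controls, as 3 wild-type libraries cannot be split into groups of 2, or a shared harvest hour.

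Genes called in all 4 mutants numbered 506 higher, with medians of 0.77 in pp1r3-2, 1.02 in topp4-1, 0.65 in topp-7m and 0.63 in the double mutant, and 493 lower, with medians of -0.86, -1.16, -0.81 and -0.79. The shared counts depended on the wild-type libraries. For pp1r3-2 and topp-7m the count was 1053 without wild-type replicate 2, 934 without replicate 3 and 1086 without topp-7m replicate 3. For pp1r3-2 and topp4-1 it was 1667, 1571 and, without pp1r3-2 replicate 3, 1592. For topp4-1 and topp-7m it was 1240 and 1154 without those wild-type libraries and 1292 and 1195 without topp-7m replicates 2 and 3. For topp4-1 and the double mutant it was 1048 and 884, and 938 without double mutant replicate 3. For pp1r3-2 and the double mutant it was 1325, 1142 and 1298 in the same order.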

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

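The tests on a mislabelled line, on depth or spread, on a missing topp4-1 allele, on the depth of replicate 3 and the replicate block in the libraries of pp1r3-2 and the double mutant alone were chosen only after the result was seen. By the interaction test the difference between the double mutant and pp1r3-2 was not the same as that between topp4-1 and wild type for 7679 genes. The genes that most marked this were PDF1.2C (interaction log2 8.72), PDF1.2A (8.22), ACT (7.33), PDF1.2B (7.02) and MSRB6 (6.77). In the other direction were LIP2 (-6.14), UGT91C1 (-5.97), HIS1-3 (-5.10), BGLU30 (-4.90) and LAC7 (-4.89). Values without single libraries are given above. In 100 splits of the libraries the real grouping gave 7566 genes in a fit of its own libraries and the highest other 4643. The splits also mix each mutation's own effect, so they cannot exclude chance.

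The first pattern is that the double mutant libraries resembled those of pp1r3-2. Further libraries of the same stock are argued against by 2 genes called over 4-fold apart without overlap, but another pp1r3-2 stock is not. That depth or spread hid the topp4-1 response is argued against by the 79.6% of genes changed at least 2-fold by topp4-1 in wild type that passed the interaction test. Whether the plants lack the topp4-1 allele cannot be told apart from a loss of its effect: edgeR called 0 genes at least 4-fold in the same direction in both backgrounds. In pp1r3-2 7 genes were called in all, 1377 had an unadjusted p under 0.05, DESeq2 called 59 and a replicate block in these libraries alone 103, and allele sequences were not used here. A shared hour of harvest stays open. The morning minus evening clock difference was 1.51 in pp1r3-2, 1.57 in the double mutant and 1.14 in topp-7m. It was 0.18 in wild type and 0.39 in topp4-1, and the hour is not given. A dependence of the topp4-1 effect on PP1R3 may be the biological explanation and stays an untested hypothesis beside these.

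The second pattern is that jasmonate genes were lower in all 4 mutants, each compared with the same 3 wild-type libraries. A single wild-type library with a high jasmonate response is argued against, since whichever wild-type library was left out at least 14 of 16 genes were still called lower in pp1r3-2, 16 of 17 in topp4-1, 15 of 17 in topp-7m and 13 of 16 in the double mutant. Wild-type plants handled or harvested differently cannot be told apart from a shared effect of the mutations. The medians of genes lower in all 4 mutants lay within 0.37 of each other on the log2 scale, but these genes were selected for being lower in all 4 against the same libraries, so this decides nothing. A shared effect of the mutations stays open and untested.

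The third pattern is that replicate 3 of the double mutant lay apart from replicates 1 and 2, at -62.7 on the second principal component. An hour of harvest of its own is argued against by clock genes, whose morning minus evening log2 difference in replicate 3 lay 0.22 from the nearer replicate, against a range of up to 0.56 within another genotype. Sequencing depth is argued against by its total count of 18.7 (in units of 1e6), between those of replicates 1 and 2. Whether topp4-1 material was mixed in cannot be told apart: over 235 genes raised at least 8-fold in topp4-1 its median log2 deviation was 0.15, against a median difference of 0.54 between replicates 1 and 2. No biological explanation was tested.

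For the comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05, with 1 split, the real one, as large each time. In fits of the compared libraries alone the real count and the highest other were 2951 and 0 for pp1r3-2, 11235 and 0 for topp4-1, 1610 and 0 for topp-7m and 1342 and 0 for the double mutant, each against wild type. They were 8097 and 0 for the double mutant against topp4-1, 3 and 0 against pp1r3-2 (so also 0 in the other splits that part all 3 same-numbered pairs), 160 and 1 for topp-7m against pp1r3-2 and 8256 and 0 for topp-7m against topp4-1.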

How the results depend on the processing

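All alternatives here were planned, except the counts of list members without wild-type replicate 3 or double mutant replicate 3 and the replicate block in the double mutant and pp1r3-2 libraries alone, which were chosen only after the result was seen. Of 1014 named gene values, 620 were past the threshold. Over 12790 alternative values 12233 kept their side of it, 446 fell short, 111 passed and 0 of the 620 reversed. RLE factors and both other filters moved no count of calls by over 1.5 times.

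DESeq2 called 59 genes for the double mutant and 799 for topp-7m against pp1r3-2, and the cause was not tested. It gave no adjusted p for 6 genes in each comparison, and for 783 in topp-7m against pp1r3-2. A fit of the compared libraries alone gave 1342 for the double mutant against wild type, 3 against pp1r3-2 and 160 for topp-7m against pp1r3-2. It raised topp4-1 against wild type to 11235 and topp-7m against topp4-1 to 8256. Replicates differed less in topp4-1 (chi-square 5.9 to 6.9 per gene) than in wild type (13.9 to 23.9), so the shared spread is doubtful. Its effect on these counts was not tested. Requiring a log2 change of at least 1, which by construction removes smaller changes, left 780 genes for pp1r3-2, 3821 for topp4-1, 517 for topp-7m and 546 for the double mutant against wild type. It left 2829 for the double mutant against topp4-1, 4 against pp1r3-2, 70 for topp-7m against pp1r3-2, 2398 against topp4-1 and 3398 for the interaction. Shared calls became 360 for pp1r3-2 and topp-7m, 492 for pp1r3-2 and topp4-1, 394 for topp4-1 and topp-7m, 340 for topp4-1 and the double mutant and 422 for pp1r3-2 and the double mutant. With the correlation between genes estimated, of the 25 lists 1 was called for topp-7m against pp1r3-2 and 0 in each other comparison, against 3 to 13 with the preset value, and the cause was not tested.

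Leaving out 1 of the libraries compared gave 2388 to 3915 genes for pp1r3-2, 9237 to 10191 for topp4-1, 1349 to 2361 for topp-7m and 1379 to 3008 for the double mutant against wild type. The range was 6961 to 9029 for the double mutant against topp4-1, 2 to 12 against pp1r3-2, 76 to 341 for topp-7m against pp1r3-2, 5732 to 7236 against topp4-1 and 6570 to 8576 for the interaction. Lists called ranged from 2 to 6, 8 to 12, 6 to 11 and 2 to 5 against wild type in the same order, 8 to 9 and 3 to 7 for the double mutant against topp4-1 and pp1r3-2, 4 to 7 and 9 to 11 for topp-7m against pp1r3-2 and topp4-1, and 8 to 14 for the interaction. Shared calls ranged from 934 to 1823, 1571 to 2527, 1154 to 1953, 884 to 1903 and 1142 to 2445 in the order of pairs above. Fewer samples can lower counts, but some rose, and the causes were not tested.

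Over all genotypes the replicate numbers do not pair the libraries: correlations of same-numbered libraries ran from -0.337 to 0.514, 9 of 30 were over 0.1, and 7 of 15 libraries correlated best with their own number. Only pp1r3-2 and the double mutant had all 3 over 0.1, and the block in their libraries alone gave 103 genes and 4 lists. With the replicate block in the fit of all libraries the counts were 4038, 10902, 2438 and 2842 against wild type in the order above, 8827 and 8 for the double mutant against topp4-1 and pp1r3-2, 360 and 7753 for topp-7m against pp1r3-2 and topp4-1, and 7873 for the interaction. Lists called with the block were 4, 10, 9, 3, 9, 3, 3, 10 and 12 in the same order. Shared calls with it were 1778, 2627, 2038, 1863 and 2269, and no count moved by over 1.5 times. For the double mutant against pp1r3-2 it ended the call of AT3G19680 (adjusted p = 0.0588) and added those of ARR7 (0.0278) and AT5G65207 (0.0472).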

Other observations

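The low-sugar and cytokinin gene lists, the split of clock genes into morning and evening sets, the test of AT5G19680 and the replicate block in the libraries of pp1r3-2 and the double mutant alone were chosen only after the result was seen. The balance of clock genes was scored without a test: the mean log2 level of 8 morning genes minus that of 7 evening genes was 0.18 ± 0.28 (SD, n = 3) in wild type, 1.51 ± 0.05 in pp1r3-2, 0.39 ± 0.10 in topp4-1, 1.14 ± 0.27 in topp-7m and 1.57 ± 0.26 in the double mutant. RVE1, CCA1 and LHY belong to the morning set. The hour of harvest is not given in the sources used here, so a change of phase, of amplitude or of level and a different hour are not separated by these values. The topp4-1 libraries (0.31 to 0.50) overlapped those of wild type (-0.09 to 0.47).

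Genes induced by low sugar, 11 in number, moved in most lines. In pp1r3-2 7 rose (camera adjusted p = 2.80e-05, adjusted p = 0.141 with an estimated correlation), in topp4-1 all 11 (8.51e-07, and 0.124 with an estimated correlation) and in topp-7m 8 (3.57e-08, and 0.0831). In the double mutant 3 rose and the list did not pass (0.0884).

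Low-sugar genes among those called lower in the double mutant than in pp1r3-2, left out of the list tested, led to the hypothesis that the low-sugar response is weaker in the double mutant. Of the 11 low-sugar genes 10 were lower there by value, with a median of -0.43, and camera gave an adjusted p of 3.90e-08 (adjusted p = 0.084 with an estimated correlation). The same libraries gave the hypothesis, so it stays open, and no member was called singly by edgeR without a block. With the replicate block in these libraries alone 7 of the 11 were called, all lower, among them MCCA (-0.72, adjusted p = 0.00262) and BCAT2 (-0.64, adjusted p = 0.00409). ARR5 led likewise to the hypothesis that the cytokinin response may be weaker in the double mutant. Of 5 other type-A response regulator genes 4 were lower by value, with a median of -0.11, and camera gave an adjusted p of 0.259 (adjusted p = 0.333 with an estimated correlation), which leaves this open. The list left out ARR5, ARR6 and ARR7. With the replicate block in these libraries alone these 3 genes were called lower, ARR5 at -0.87 (adjusted p = 0.00511), ARR6 at -1.03 (adjusted p = 0.0447) and ARR7 at -0.71 (adjusted p = 0.00743). The same list of 5 was lower in topp-7m than in pp1r3-2 (all 5 by value, 1 called, median -0.39, camera adjusted p = 0.00457, adjusted p = 0.041 with an estimated correlation).

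The transcript of AT5G19680 (chromosome 5, 6649574 to 6652046), chosen after its values were seen, was low in both lines that carry pp1r3-2. Its level was 28.1 ± 1.08 CPM in wild type, 32.8 ± 4.02 CPM in topp4-1 and 28.6 ± 1.88 CPM in topp-7m, against 8.6 ± 0.167 CPM in pp1r3-2 and 8.12 ± 1.09 CPM in the double mutant. It changed by -1.72 ± 0.11 in pp1r3-2 against wild type (adjusted p = 2.22e-07) and by -2.01 ± 0.11 in the double mutant against topp4-1 (adjusted p = 1.03e-08). It may be the gene disrupted in pp1r3-2, but 13 genes, itself included, were lower at least 2-fold in pp1r3-2 than in wild type and topp-7m and in the double mutant than in topp4-1, and not called lower in topp4-1 or topp-7m against wild type. Among the 13 it had the smallest adjusted p in pp1r3-2, the next being that of PAE9 (0.000599), while ATGRP9 had a smaller one in the double mutant against topp4-1 (4.45e-09). This standing does not show which gene is disrupted.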
